A study of Canis lupus familiaris with 8 samples.

How the data were processed

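Total RNA from frozen anterior mitral valve leaflets of 4 control and 4 affected dogs was biotin-labelled by an Affymetrix protocol and hybridised to 1 array per dog, per the labels. The deposited values are probe set signals on a linear intensity scale, made with MAS5, per the submitters' processing notes. The version of MAS5, its detection calls and any filter are not given in the sources used here. MAS5 combines the perfect match and mismatch probes of a probe set into 1 signal, so values near the background are imprecise. The trimmed mean over all rows, leaving out 2% at each end, was 500.1 on every array, so the arrays had already been scaled to a common level. Such scaling assumes that total signal is alike, and a tissue that differs in its most abundant transcripts moves all other values.

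The table held 23913 rows, of which 77 were array control probe sets. Gene names came from the platform annotation. It gave 1 symbol for 10549 rows, several for 138 and none for 13226, and only rows with 1 symbol were named. For 10046 of the named rows the gene identifier was found in a RefSeq gene table of the dog assembly UU_Cfam_GSD_1.0, and 0 symbols needed updating. No coordinates are given, since the annotation names no genome build.

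Signals were scaled to a common trimmed mean, which changed no array by more than a factor between 0.999988 and 1.00001. Values under a floor of 34.2, the 20th percentile of all signals, were set to the floor (5.10 on the log2 scale), and log2 was taken. A probe set was tested if at least 4 of 8 arrays lay above that array's own 40th percentile. Values at the floor are upper bounds, so a difference against a group at the floor is a lower bound and is given as at least that many times. The groups were compared with limma (version 3.58.1 in R 4.3.3), lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the 14705 tested probe sets and a threshold of 0.05. Differences are log2 signal, affected minus control, and each error marked SE or following a difference is the standard error from limma with 4 dogs per group.

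Gene lists were tested with camera of limma at a preset correlation of 0.01, two-sided, on the brightest probe set of each of 5438 genes, with Benjamini-Hochberg adjustment over the lists. Of 36 lists, covering matrix, valve signalling, inflammation, metabolism and markers of the cell types a leaflet could hold, 32 had at least 5 measured genes. A preset correlation takes the genes of a list as nearly independent. Camera with an estimated correlation and fry were run beside it: with an estimated correlation 0 of the 32 lists passed and the smallest adjusted p was 0.347, and fry, which asks whether a list's genes move on balance in 1 direction, called 0, with a smallest adjusted p of 0.0665. Fry's mixed test, which asks whether genes change in either direction, called 4. Over the 11 lists called at the preset correlation, the estimated correlation ranged from -0.0136 to 0.768. For integrins (-0.0136) and serotonin handling (0.0167) it was near the preset, so correlation within these lists alone did not end their calls. Each dog's mean list signal and the array-level measures were compared by two-sided exact permutation tests over 70 splits, which cannot give a p under 0.0286.

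The design, the tests, the lists and the rule for naming genes were fixed before the data were examined. The rule named the 10 genes per direction with the largest change among those past the threshold or, since none passed, those with the smallest unadjusted p among probe sets with 1 symbol and no overlap between the groups, 1 per gene. It also named the 3 members with the smallest p of each list that the text describes, with every member past the threshold where there were 5 or fewer, and 27 genes of valve disease whatever their values. MARCO, ADIPOQ and the genes of the lists that were too short to test were named after their values were seen.

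The tests were tried on simulated data with the means of these arrays. In the probe set simulation each probe set kept its own spread, and in the list simulation every gene had the same spread. With 200 probe sets changed among 14705, 0% were recovered at a log2 change of 1, 63.1% at 2 and 95.9% at 4, with 5.6 and 8.6 false calls on average at 2 and 4. A list of 20 genes shifted by a log2 change of 1 was found in 20 of 20 runs over 5438 genes, and 1 of 600 unshifted lists was called. The simulated genes were independent within a list and alike in spread, so this does not give the power for the real lists.

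The alternatives were quantile normalization, median centring, values as deposited, no filter and a stricter filter, no floor, a floor at the 40th percentile and a pseudocount in its place, eBayes without a trend and with a robust prior, array weights, the replicate number as a block, other thresholds, other list tests, and leaving out each dog in turn. Added after seeing the data were the mean of the cardiac muscle list as a covariate, leaving out control 2 and affected 3 together (the dogs at both ends of that list), camera with an estimated correlation together with the other settings, exact permutation of list means and the signal of spiked-in controls. Age, sex, disease stage and scan batch of the dogs are not given in the sources used here and were not modelled. The labels call the arrays biological replicates, which was taken as 1 dog per array.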

Results

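RNA was measured in the anterior mitral valve leaflet of 8 dogs, 4 controls and 4 affected by degenerative mitral valve disease, a thickening and distortion of the leaflets that is common in older dogs of small breeds. Each dog gave 1 Affymetrix array. All 4 control dogs were beagle crosses. The affected dogs were a Lhasa apso (affected 1), a Miniature poodle (affected 2), a Dachshund (affected 3) and another Miniature poodle (affected 4), so breed and disease changed together and could not be told apart. Every array had the same trimmed mean signal of 500.1, and the median signal ranged from 124 in affected 3 to 191 in affected 2. Precision was limited by the number of arrays. Of 23836 probe sets other than controls, 14705 were bright enough to be tested, and 7855 of these had 1 gene symbol.

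The comparison asked which genes differ between diseased and control leaflets. Lists of genes of macrophages and monocytes, of inflammatory signalling, of antigen presentation, of complement and of the endothelium had higher signals in affected leaflets in camera at a preset correlation, a call that each list lost with an estimated correlation (smallest adjusted p = 0.347 over the 32 lists). Lists of oxidative phosphorylation, fat cells, cell junctions and heart muscle had lower signals in the same test, with adjusted p from 0.455 to 0.815 with an estimated correlation. The oxidative phosphorylation, cell junction and heart muscle calls also ended without control 2, and the heart muscle median turned without affected 3. The greatest differences among the named genes were in the acute phase protein SAA1, which was 35.3 times as high in affected dogs, and in the chemokine CXCL8, which was 27.2 times as high. The size for CXCL8 is loose, since 3 controls lay at or near the floor and its log2 difference of 4.77 ranged from 3.68 with a floor at the 40th percentile to 5.93 without control 1. No single gene is called, because no probe set passed limma at an adjusted p of 0.05 in either direction and the smallest adjusted p was 0.238. At an unadjusted p under 0.05, 591 probe sets were higher and 560 lower in affected dogs, where 735 in all would be expected with no effect. The groups did not overlap for 345 probe sets that were higher and 340 that were lower, which is 4.66% of those tested against 2.86% by chance.

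Macrophage and monocyte markers rose as a list. All 22 measured members were higher in affected dogs, with a median log2 difference of 1.88 and a camera adjusted p of 3.76e-16. The call was lost, with adjusted p = 0.347 with an estimated correlation. No member passed over all probe sets, and 13 passed when adjusted over the list alone. FCER1G, the shared signalling chain of Fc receptors, differed by 2.91 ± 0.44 (log2, SE) with 3 of 4 controls at the floor, CD14, a receptor for bacterial lipopolysaccharide, by 2.09 ± 0.45 and the Fc receptor FCGR1A by 3.53 ± 0.77. The scavenger receptor MARCO was at the floor in all 4 controls and was at least 8.11 times as high in affected dogs. The mean signal of the list was higher in each affected dog than in every control (exact permutation p = 0.0286, the smallest that 4 against 4 dogs can give, and 0.183 adjusted over 32 lists). Control 2 had the lowest value of this list, and without that dog the median was 1.09, still past the threshold with an adjusted p of 6.03e-14 in camera (adjusted p = 0.329 with an estimated correlation).

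Cytokines, chemokines and acute inflammation rose as a list, with 21 of 24 members higher, a median of 1.12 and a camera adjusted p of 5.49e-07 (adjusted p = 0.455 with an estimated correlation). The exact permutation p for the mean signal of this list per dog was 0.0571. No member passed over all probe sets and 3 passed adjusted over the list alone. SAA1 differed by 5.14 ± 0.73, CXCL8, which attracts neutrophils, by 4.77 ± 1.20 and VCAM1, an adhesion molecule for leukocytes, by 1.63 ± 0.47. CXCL8 had another probe set at 2.81 ± 1.25 and overlapping groups, since control 1 had a log2 signal of 9.85 and the mean of the other controls was 5.19. Antigen presentation rose as a list, with 11 of 12 members higher, a median of 1.33 and a camera adjusted p of 0.000131 (adjusted p = 0.486 with an estimated correlation). The exact permutation p for its mean signal per dog was 0.0857. Its members TAP1, which loads peptides for class I molecules, the class I gene DLA-79 and the immunoproteasome subunit PSMB8 differed by 1.31 ± 0.41, 1.39 ± 0.54 and 0.79 ± 0.40, and 0 members passed adjusted over the list alone. Complement rose as a list, with all 13 members higher, a median of 0.70 and a camera adjusted p of 0.00182 (adjusted p = 0.455 with an estimated correlation). C1QC differed by 1.95 ± 0.86, C2 by 1.28 ± 0.62 and the complement inhibitor CD59 by 0.74 ± 0.32, and 0 members passed adjusted over the list alone. Without control 2 C1QC was at 1.17, TAP1 at 0.87 and PSMB8 at 0.43, without affected 4 C2 was at 0.62, and without affected 1 CD59 was at 0.48. The macrophage list shares C1QA and C1QC with complement, CTSS with antigen presentation and ITGAM with integrins, so these lists are not independent of it. Without control 2 the medians of antigen presentation and complement were 0.45 and 0.26, past the threshold at the preset correlation but not with an estimated one (adjusted p = 0.475 and 0.349).

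Endothelial markers rose as a list, with 12 of 13 members higher, a median of 0.63 and a camera adjusted p of 1.89e-05 (adjusted p = 0.347 with an estimated correlation). 4 members passed adjusted over the list alone and 0 over all probe sets. NOS3, the endothelial nitric oxide synthase, differed by 1.07 ± 0.29, the TGF-beta co-receptor ENG by 1.27 ± 0.35 and the junctional adhesion molecule PECAM1 by 1.01 ± 0.34. Without control 4 the median was 0.99. Integrins rose as a list, with 12 of 16 members higher, a median of 0.20 and a camera adjusted p of 0.0277 (adjusted p = 0.347 with an estimated correlation). The 3 members with the smallest p were ITGB2 at 1.52 ± 0.33, ITGA5, a subunit of the fibronectin receptor, at 1.79 ± 0.41 and ITGAM, which forms a receptor of leukocytes with ITGB2, at 1.38 ± 0.35. 3 members passed adjusted over the list alone and 0 over all probe sets. The call ended without affected 3 (adjusted p = 0.0852, median 0.36) and without affected 4 (adjusted p = 0.0547, median 0.07), and without control 1 the median was 0.12. It also ended with no filter on dim probe sets (adjusted p = 0.0927) and in camera on ranks (adjusted p = 0.135). Serotonin handling and receptors rose as a list, with 9 of 10 members higher, a median of 0.33 and a camera adjusted p of 0.0184 (adjusted p = 0.347 with an estimated correlation). Those 10 are part of 30 listed genes, and the transporter SLC6A4, the synthesis enzyme TPH1 and the receptor HTR2A were not named on the array. The list also holds signalling kinases such as PRKCB, so its rise does not stand for serotonin handling alone. DDC, which makes serotonin from its precursor, differed by 1.24 ± 0.36, the serotonin receptor HTR2B by 2.04 ± 0.66 and the kinase PRKCB by 0.81 ± 0.42, and 0 members passed adjusted over the list alone. The serotonin call ended without control 2 (adjusted p = 0.0711, with PRKCB at 0.53) and without affected 3 (adjusted p = 0.0557), and also with no filter on dim probe sets (adjusted p = 0.108), array weights (adjusted p = 0.0945) and the cardiac muscle covariate (adjusted p = 0.0603). For endothelial markers, complement, integrins and serotonin handling, as for macrophage markers, all 4 affected dogs lay above all 4 controls. The exact permutation p was 0.0286 for each, and 0.183 adjusted over the 32 lists.

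**Figure D1:**
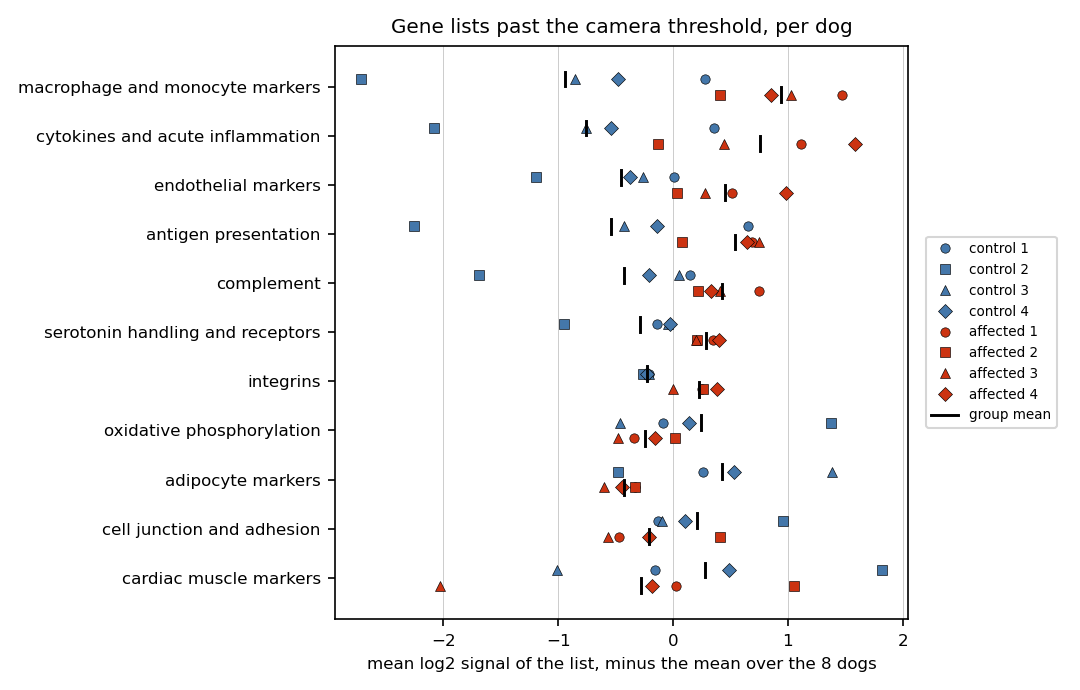
Each point is 1 dog's mean log2 signal over a gene list, minus the mean over the 8 dogs, for the 11 lists past the threshold, with controls in blue, affected dogs in red and a black bar at each group mean. Control 2 has the lowest value of the macrophage list at -2.716 and the highest of the cardiac muscle list at 1.817, and the affected dogs span 0.412 to 1.469 in the macrophage list.

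Oxidative phosphorylation fell as a list, with 39 of 40 members lower, a median of -0.47 and a camera adjusted p of 1.99e-06 (adjusted p = 0.815 with an estimated correlation). The exact permutation p for its mean signal per dog was 0.314. The complex I subunits NDUFV1, NDUFA2 and NDUFV2 differed by -0.89 ± 0.37, -0.62 ± 0.28 and -0.77 ± 0.39, and 0 members passed adjusted over the list alone. Cardiac muscle markers fell as a list, with 20 of 23 members lower, a median of -0.58 and a camera adjusted p of 0.0277 (adjusted p = 0.815 with an estimated correlation). The calcium channel CACNA1C, the sarcomere protein MYOZ2 and the stress-responsive ANKRD1 differed by -0.61 ± 0.30, -1.16 ± 0.64 and -1.05 ± 0.66, and 0 members passed adjusted over the list alone. Both calls ended without control 2, where the medians were -0.089 (adjusted p = 0.254) and -0.07 (adjusted p = 0.912). Without affected 3 the median of the cardiac muscle list turned to 0.11 (adjusted p = 0.991), and it was -0.96 without control 3 and -0.94 without affected 2. Without control 2 NDUFV1, NDUFA2, NDUFV2, MYOZ2 and ANKRD1 were at -0.49, -0.37, -0.39, -0.64 and -0.50. The cardiac muscle call also ended with no filter on dim probe sets (adjusted p = 0.0787), a stricter filter (adjusted p = 0.0581) and array weights (adjusted p = 0.117). The mean log2 signal of the cardiac muscle list was 13.47 in control 2 and 9.62 in affected 3, and averaged 11.93 ± 1.19 (SD, n = 4) in controls and 11.37 ± 1.28 (SD, n = 4) in affected dogs (exact permutation p = 0.571). Cell junction and adhesion genes fell as a list, with 13 of 16 members lower, a median of -0.31 and a camera adjusted p of 0.0277 (adjusted p = 0.8001 with an estimated correlation). The exact permutation p for their mean signal per dog was 0.257. The tight junction protein TJP1 differed by -0.57 ± 0.22, JAM3 by -0.71 ± 0.33 and CLDN10 by -1.04 ± 0.49, and 0 members passed adjusted over the list alone. The cell junction call ended without control 2 (adjusted p = 0.455, median -0.19, with CLDN10 at -0.65), without affected 1 (adjusted p = 0.0625, with JAM3 at -0.43) and without affected 3 (adjusted p = 0.132). It also ended with no filter on dim probe sets (adjusted p = 0.0548), array weights (adjusted p = 0.196) and the cardiac muscle covariate (adjusted p = 0.129).

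Adipocyte markers fell as a list, with 8 of 11 members lower, a median of -0.48 and a camera adjusted p of 0.00320 (adjusted p = 0.455 with an estimated correlation). The exact permutation p for their mean signal per dog was 0.114. The 3 members that passed adjusted over the list alone handle lipid in many tissues besides fat, and 0 passed over all probe sets. They were CD36, a fatty acid transporter, at -2.22 ± 0.45, SCD, a fatty acid desaturase, at -1.15 ± 0.26 and LPL, a lipase of lipoproteins, at -1.70 ± 0.39. Each was lower in all 4 affected dogs than in all 4 controls. The other 2 probe sets of LPL differed by -1.97 ± 0.51 and -0.59 ± 0.53, and the other of SCD by -0.98 ± 0.50. ADIPOQ, a hormone made by fat cells, differed by -2.82 ± 1.36, with control values from the floor in control 2 to 13.26 in control 3. The adipocyte call ended without control 3 (adjusted p = 0.0703, median -0.24), and without control 2 the median was -0.79.

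Among single genes, 10 in each direction had the smallest unadjusted p and no overlap between the groups, and none of the 20 passed the threshold. Besides SAA1 and FCER1G, the genes with higher signals were S100P, a calcium-binding protein, at 3.88 ± 0.64, LOC403585, for which the reference lists SAA as another name, at 3.76 ± 0.66, and UPP1, an enzyme of uridine breakdown, at 3.47 ± 0.65. CALCA, the gene of calcitonin and a related neuropeptide, differed by 2.50 ± 0.41, IGFBP2, which binds insulin-like growth factors, by 2.32 ± 0.43 and RGS2, a brake on G protein signalling, by 1.79 ± 0.32. EPHA3, an ephrin receptor, differed by 1.73 ± 0.32 and MEGF9 by 1.23 ± 0.23. FCER1G and LOC403585 were at the floor in 3 of 4 controls and CALCA in 2, so the sizes of these differences depend on the floor. They were 1.69, 2.44 and 1.52 with a floor at the 40th percentile and 4.20, 4.15 and 3.14 with no floor. The 6 tested probe sets of LOC403585 ranged from -0.74 to 4.74 and most of them can share signal with related sequences. The genes with lower signals were SELENBP1, a selenium-binding protein, at -1.79 ± 0.26, TCN2, a carrier of vitamin B12, at -2.24 ± 0.42, and CD36, SCD and LPL with the values above. CYP3A26, a drug-metabolising cytochrome, differed by -1.46 ± 0.31, ENPP2, which makes lysophosphatidic acid, by -1.61 ± 0.34 and the peroxide-degrading enzyme CAT by -1.37 ± 0.30. PRXL2A differed by -1.31 ± 0.30 and the aldehyde reductase AKR7A2 by -1.59 ± 0.37. The other 2 probe sets of TCN2 differed by 0.52 ± 0.30 and 0.12 ± 0.24, against the direction of the first. The other probe set of CAT, which was brighter, differed by -0.76 ± 0.24. Those of SELENBP1, ENPP2 and RGS2 differed by -1.43 ± 0.27, -2.03 ± 0.60 and 2.23 ± 0.56.

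**Figure D2:**
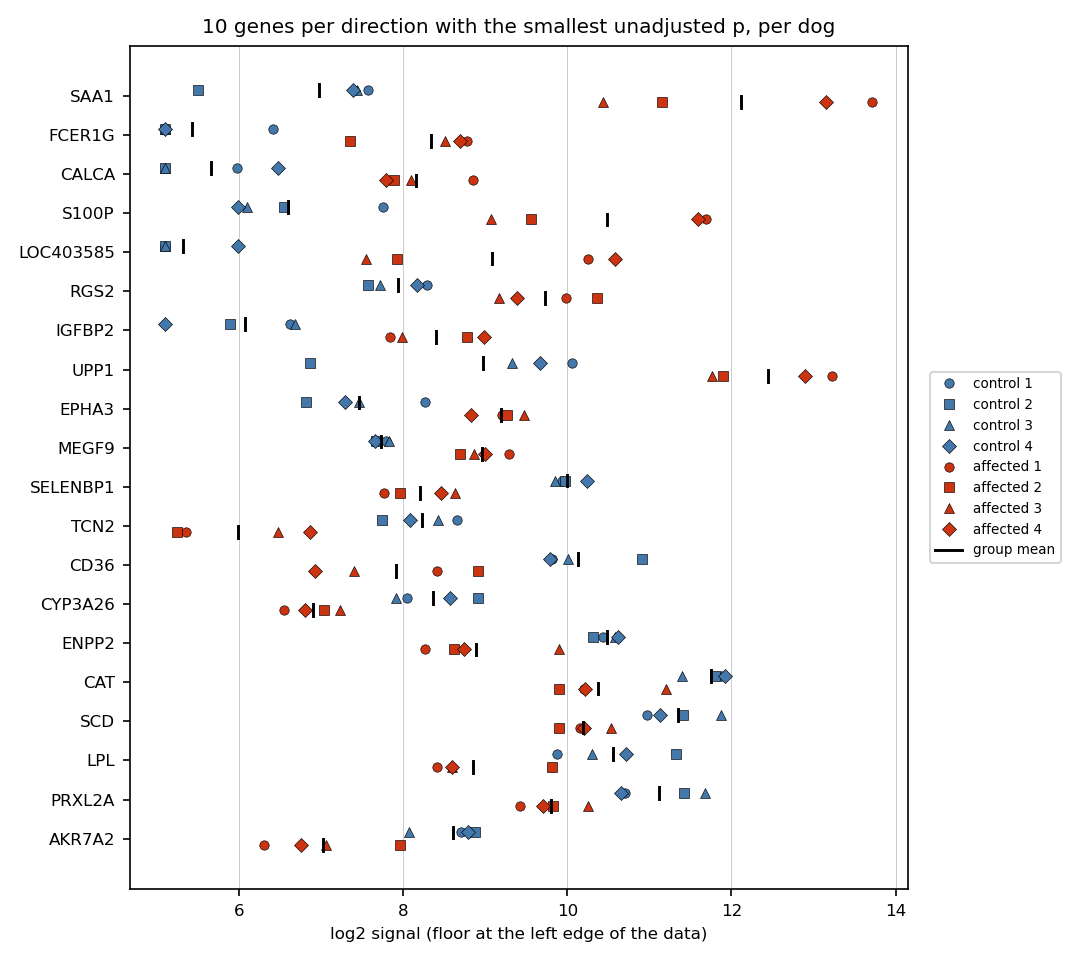
Each point is 1 dog's log2 signal for the 10 genes per direction with the smallest unadjusted p, with controls in blue, affected dogs in red and a black bar at each group mean. The affected dogs lie between 10.43 and 13.72 for SAA1 and the controls between 5.50 and 7.57.

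Of 27 genes named in advance for their part in valve disease, 19 were tested and 8 were not named on the array. None passed over all probe sets or adjusted over the list alone, where the smallest adjusted p was 0.122. HTR2B differed by 2.04 ± 0.66 and the protease inhibitor TIMP1 by 2.24 ± 0.76, each with all affected dogs above all controls, and without control 2 these were 1.35 and 1.34. The gelatinase MMP9 differed by 2.54 ± 0.92 and the cytokine IL6 by 3.03 ± 1.29, with overlapping groups. IL6 was 9.88 in control 1 and averaged 5.51 in the other controls, and without affected 4 its difference was 1.92. TGFB1 differed by 0.74 ± 0.36, the cytoskeletal protein VIM by 0.53 ± 0.27, the smooth muscle actin ACTA2 by 0.53 ± 0.48 and IL18 by 0.60 ± 0.58. Single dogs moved several of these: ACTA2 was at 0.16 without affected 1 and 0.88 without affected 4, IL18 at 0.13 without control 2 and 1.07 without control 1, and VIM at 0.35 without affected 1. Quantile normalization put VIM at 0.11, and a floor at the 40th percentile put IL18 at 0.18. For the matrix genes the differences were smaller than their errors, at 0.30 ± 0.67 for COL1A1, 0.36 ± 0.38 for COL1A2, -0.0082 ± 0.62 for COL3A1, -0.15 ± 0.25 for ELN and -0.36 ± 1.27 for ACAN. The same held for MMP2 at 0.14 ± 0.79, MMP14 at -0.11 ± 0.78, TGFB2 at 0.27 ± 0.33, DES at 0.33 ± 0.79 and SOX9 at -0.59 ± 0.77, while BMP2 differed by 0.35 ± 0.34 and was at 0.033 without control 2. Without control 2, COL1A1 was at -0.52, COL1A2 at -0.07, MMP2 at -0.77 and TGFB2 at -0.02, so their direction turned. Probe sets of a gene also disagreed, from -0.22 to 0.36 over the 4 of COL1A2 and from -0.53 to 0.52 over the 4 of COL3A1.

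**Figure D3:**
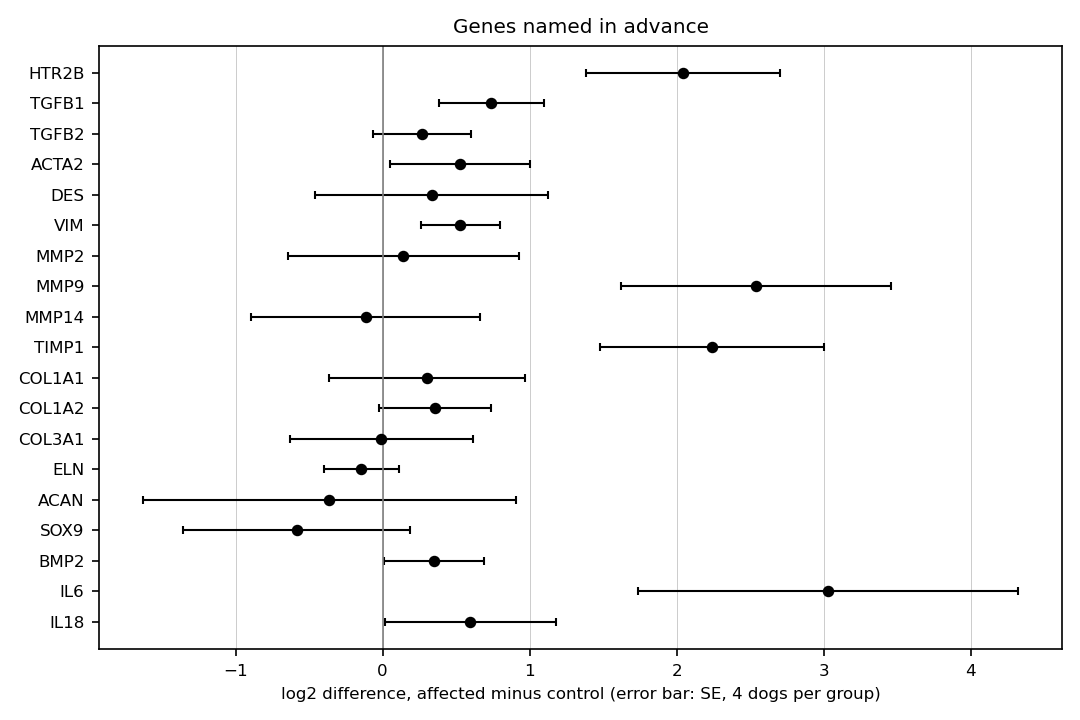
Each point is the log2 difference of affected minus control for 1 of the 19 genes named in advance, and its bar is the standard error from limma over 4 dogs per group. IL6 has the largest difference at 3.03, and the bar of COL3A1 at -0.0082 crosses 0.

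The remaining 21 lists were not past the threshold, and each value in brackets after a median is the camera adjusted p of that list. Among matrix lists, fibrillar and network collagens had a median of 0.19 (camera adjusted p = 0.877), collagen processing 0.12 (0.182), elastic fibre and microfibril 0.16 (0.615), proteoglycans and hyaluronan 0.27 (0.175), other matrix proteins 0.0039 (0.745) and matrix proteases and inhibitors 0.23 (0.0946). Within them the basement membrane chain COL4A1 differed by 0.88 ± 0.28, COL4A2 by 0.76 ± 0.27 and COL4A6 by -0.72 ± 0.25. The crosslinking enzyme TGM2 differed by 1.18 ± 0.44, the fibrillins FBN1 and FBN2 by 0.95 ± 0.38 (0.58 without control 2) and -1.10 ± 0.46, and the cathepsin CTSB by 0.80 ± 0.29. TGF-beta and BMP signalling had a median of 0.27 (0.0946), with 2 of 19 members past the threshold adjusted over the list alone. Its leading members were BMP6 at 1.98 ± 0.48, ENG and SMAD5 at -0.93 ± 0.29. Myofibroblast and smooth muscle genes had a median of 0.40 (0.176), with FLNA, the filamin that cross-links actin, at 0.92 ± 0.35 and ACTG2 at 1.09 ± 0.47. Chondrogenic and osteogenic genes had a median of -0.06 (0.706), with the cartilage matrix gene CILP at -2.13 ± 0.65. Wnt signalling had a median of 0.08, a mean of -0.27 and a test pointing down (0.613), with the Wnt inhibitor WIF1 at -1.85 ± 1.04. Without control 2, camera called collagens lower (median -0.53, adjusted p = 0.0177), chondrogenic and osteogenic genes lower (median -0.23, adjusted p = 0.0234), myofibroblast genes higher (median 0.49, adjusted p = 0.0177) and glycolysis and hypoxia higher (median 0.33, adjusted p = 0.0365). With an estimated correlation these 4 calls were lost without control 2, with adjusted p of 0.475, 0.329, 0.775 and 0.777 in that order. At the preset correlation some of these lists were past the threshold in other settings. With an estimated correlation no list was called in any of 22 such settings (other scaling, filters, floors, priors, weights, the block, the covariate and left-out dogs), where the smallest adjusted p was 0.245. It was not run with the mean over probe sets or on ranks. TGF-beta and BMP signalling was called higher with a stricter filter (adjusted p = 0.0221), with the mean over the probe sets of a gene (adjusted p = 0.0450), without control 1 (adjusted p = 0.0270) and without control 4 (adjusted p = 0.0433). Matrix proteases and inhibitors were called higher with median centring (adjusted p = 0.0488), with the mean over probe sets (adjusted p = 0.0243), without control 1 (adjusted p = 0.0148), without control 4 (adjusted p = 0.0269) and without affected 2 (adjusted p = 0.0150). Myofibroblast and smooth muscle genes were called higher with a stricter filter (adjusted p = 0.0301), the cardiac muscle covariate (adjusted p = 0.00147) and without affected 4 (adjusted p = 0.0442).

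Among the other lists, again with the camera adjusted p in brackets after each median, interferon response had a median of 0.25 (camera adjusted p = 0.132), lymphocyte markers 0.27 (0.706), Schwann cell and neuronal markers 0.06 (0.706), valve development factors 0.0035 (0.706) and cell cycle 0.04 (0.877). Ribosomal proteins had a median of 0.15 (0.0946), endoplasmic reticulum folding and stress 0.10 (0.199), immediate-early and heat shock genes 0.06 (0.292) and oxidative stress defence 0.04 (0.877). At the preset correlation, interferon response was called higher without control 1 (adjusted p = 0.0105) and without affected 2 (adjusted p = 0.0332), ribosomal proteins without control 4 (adjusted p = 0.0122), without affected 2 (adjusted p = 0.00226), with the mean over probe sets (adjusted p = 0.0334) and on ranks (adjusted p = 0.0380), endoplasmic reticulum folding without affected 2 (adjusted p = 0.00266) and immediate-early genes without control 1 (adjusted p = 0.0257). Without those dogs these calls were lost with an estimated correlation, with adjusted p = 0.552 and 0.717 for interferon response, 0.850 and 0.745 for ribosomal proteins, 0.717 for endoplasmic reticulum folding and 0.609 for immediate-early genes, and it was not run with the mean over probe sets or on ranks. Glycolysis and hypoxia had a median of 0.03 and a mean of -0.02 with a test pointing up (0.745). The renin-angiotensin, endothelin and natriuretic peptide list had a median of -0.12 and a mean of 0.12 with a test pointing up (0.706). Members with small p in these lists included GAP43, a protein of growing axons, at 1.58 ± 0.35, the phagocyte oxidase CYBB at 2.07 ± 0.47, DNAJC3, a chaperone of the endoplasmic reticulum, at 1.24 ± 0.31, and the vasoconstrictor EDN1 at 1.23 ± 0.44. For markers of mast cells, neutrophils and erythroid cells and platelets, only 1, 1 and 3 genes were measured, and these lists were not tested. MS4A2, a mast cell receptor chain, differed by 0.74 ± 0.37 and the neutrophil receptor CXCR2 by 0.35 ± 0.38. The erythroid and platelet genes GYPC, ITGA2B and GP1BA differed by -0.32 ± 0.36, 0.06 ± 0.34 and 0.36 ± 0.46, and no sex-linked gene of the list was measured.

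Control 2 stood apart from the other arrays. On the first principal component, which held 34.0% of the variance, it lay at 100.8 and the other arrays between -49.5 and 28.1. Its median correlation with the other arrays was 0.802 across probe sets, which are not independent replicates, against 0.875 to 0.904 for the others. No array-level measure differed between the groups at a p under 0.05 in an exact permutation test. The log2 ratio of 3' to 5' signal for GAPDH was 0.16 ± 0.18 (SD, n = 4) in controls and 0.37 ± 0.19 (SD, n = 4) in affected dogs (exact permutation p = 0.171). For beta-actin it was -0.70 ± 0.81 and -0.31 ± 0.63 (exact permutation p = 0.486). The share of probe sets at the floor was 20.4% ± 1.39 in controls and 19.4% ± 2.996 in affected dogs (exact permutation p = 0.6), and the median signal was 145.8 ± 9.73 and 155 ± 28.2 (exact permutation p = 0.571). The mean log2 signal of spiked-in hybridisation controls was 11.10 ± 0.31 and 11.60 ± 0.77 (exact permutation p = 0.286), with the highest values, 12.53 and 11.92, in affected 1 and 2. Adjusted over the 7 measures, every p was at least 0.700.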

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

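Of the tests in this part, those of the macrophage markers against control 2, against the share of heart muscle and against labelled target were chosen after the result was seen, as were the cardiac muscle covariate, the choice of CD36, LPL and SCD, which were picked by their p, and the fat covariate for them. A value was singled out when the gap from the highest or lowest dog of a group to its neighbour exceeded Dixon's 95% critical value as a share of that group's range. Over 322 groups of 4 dogs (lists, named genes and array measures), 37 met this, where chance gives about 1 in 20, or 16.1. The groups share dogs and genes, so this is no test of an excess. Control 2 was the dog in 21 of the 37, each time as the lowest.

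Control 2 was lowest among controls in 8 lists: fibrillar and network collagens (gap over range 0.876), collagen processing (0.852), proteoglycans and hyaluronan (0.951), other matrix proteins (0.880), matrix proteases and inhibitors (0.880), TGF-beta and BMP signalling (0.900), serotonin handling (0.880) and Wnt signalling (0.920). It was also lowest in 13 named genes. The gaps were 0.911 for SAA1, 0.835 for MMP2, 0.897 for TIMP1, 0.904 for COL3A1, 0.901 for SOX9, 0.920 for BMP2, 0.928 for LOXL3, 0.830 for MFAP4, 0.859 for SRGN, 0.852 for THBS1, 0.854 for THBS2, 0.907 for WIF1 and 0.879 for SEC61A1. Control 1 was highest in IL6 (0.860), CXCL8 (0.957), JUNB (0.907) and the share of probe sets at the floor (0.895). For FCER1G control 1, and for LOC403585 control 4, was the sole control above the floor, so the gap was 1. Affected 2 was lowest in matrix proteases and inhibitors (0.895), antigen presentation (0.840) and PSMB8 (0.989), and highest in LPL (0.871) and MYOZ2 (0.847). Affected 3 was highest in COL3A1 (0.889), SOX9 (0.910) and CACNA1C (0.851). Affected 1 was highest in CTSB (0.837) and lowest in MGST2 (0.838), where it was at the floor.

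Macrophage and monocyte markers were higher in affected dogs, with a difference of 1.88 in the mean list signal. Control 2 alone is argued against as the whole cause, since the median without it was 1.09, above a bound of 0.94. That bound was set after the result was seen. Without control 2 the list was past the camera threshold at the preset correlation (adjusted p = 0.329 with an estimated correlation, which also ends the call with all dogs). A different share of heart muscle, which would move all leaflet genes alike, is argued against as well: the list minus the mean of 4 matrix lists was higher in each affected dog than in every control and differed by 1.72, and less labelled target on affected arrays is argued against by the 2 affected arrays whose spiked-in controls lay within the control range, which showed a difference of 1.89. Of the 35 splits of the 8 dogs, 1, the real split, gave a difference as large (1.88, against 1.82 for the highest other), which is the smallest share that 35 splits can give; adjusted over the 32 lists the exact permutation p was 0.183, so chance is not excluded once the choice among lists is counted. A greater share of macrophages in diseased leaflets may be a biological difference, as a hypothesis, while chance, breed and age stay open.

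Oxidative phosphorylation genes were lower in affected dogs, with a median of -0.47, but without control 2 the median was -0.089 and the call ended, which is what control 2 alone as the source would give. With the cardiac muscle list as a covariate the median was -0.26, close to the bound of -0.24 set for it, and the mean of the list differed by -0.26 ± 0.27 (SE), so a different share of heart muscle and a difference in leaflet cells cannot be told apart with 8 dogs. Over the 8 dogs, in the 1 relation of this kind that was computed, the 2 lists went together (Pearson r = 0.819, permutation p = 0.00746; Spearman rho = 0.905, permutation p = 0.00437; r = 0.801 without the 2 dogs farthest from the median of the cardiac muscle list). The 3 cardiac muscle genes with the highest mean signal, MYL4, ACTC1 and TNNC1, which probe signals do not rank by transcript level, had log2 signals of 15.10, 14.40 and 14.96 in control 2 and 12.79, 12.78 and 11.99 in affected 3. Affected 2, at 15.17, 14.89 and 14.92, was about as high as control 2, and 1 of the 23 measured genes of the list is in another list.

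CD36, LPL and SCD were lower in affected dogs, with -2.22 ± 0.45, -1.70 ± 0.39 and -1.15 ± 0.26, although another probe set of LPL differed by only -0.59 ± 0.53. With the mean of ADIPOQ, CIDEA and DGAT2 as a covariate the median of the 3 genes was -2.04 and each stayed below 0 by over 2 SE. This cannot decide on a different share of fat tissue. Control 2 had the lowest mean of those fat genes (6.93) but the highest CD36 (10.91), LPL (11.32) and heart muscle signal. Under the fat covariate CD36 and LPL moved away from 0, to -2.56 and -2.04, and SCD moved to -1.04. Fat and heart muscle were not fitted together. A different share of heart muscle alone is argued against as the whole cause only weakly. The 3 genes were picked by their p. Heart muscle signal differed by only -0.56 between the groups (exact permutation p = 0.571), so the covariate could take away little. With the cardiac muscle covariate the median was -1.49 and each gene stayed below 0 by over 2 SE. Breed and age stay open. Less lipid uptake in diseased leaflets may be a biological difference, as a hypothesis that was found on these dogs and was not tested.

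Chance could not be excluded for the 2 counts over all genes. The real split gave 1151 probe sets at an unadjusted p under 0.05, and 6 of the 35 splits gave as many or more, up to 2444. That highest split set controls 1, 3 and 4 with affected 3 against control 2 with the other affected dogs, and called 71 probe sets at an adjusted p of 0.05 where the real split called 0, which points to a structure of the samples other than disease. The real split gave 11 called lists in camera, and 14 of the 35 splits gave as many or more, up to 18.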

How the results depend on the processing

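The cardiac muscle covariate, leaving out control 2 and affected 3 together, an estimated correlation in other settings and exact permutation of list means were chosen after seeing the data. The cause of each change below was not tested.

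No probe set passed in 21 of 24 settings. A further cut on the log2 change could only keep the main count of 0, and the values as deposited barely differ from the scaled ones. With the replicate number as a block 4 passed (SAA1, S100P, UPP1 and a probe set with no symbol). Same-numbered dogs deviated from their group means with correlations of -0.12, 0.41, 0.02 and -0.01, so the numbers do not pair the dogs and not every dog correlated best with its own number. The smallest adjusted p ranged from 0.00803 to 0.835 over the settings. Leaving out each dog gave 0 to 1 calls (1 without control 1, the same unnamed probe set), 380 to 1006 probe sets higher and 314 to 834 lower at an unadjusted p under 0.05. Array weights gave 896 higher and 1071 lower, and the muscle covariate 863 lower. With control 2 and affected 3 left out, 128 passed, 29 higher and 99 lower, with 1153 higher and 1287 lower at an unadjusted p under 0.05.

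Camera called 7 lists with no filter (2 lower), 2 lower with array weights and 2 lower with the muscle covariate, and 0 lists with an estimated correlation (with all dogs or in any of 22 other settings), with fry or with exact permutation of list means, in either direction. Leaving out each dog gave 7 to 15 called lists, 5 to 11 higher and 2 to 4 lower. Over 26 settings, not counting the estimated correlation in other settings and the permutation, the 11 called lists kept direction and call in 234 of 285 checks, lost the call in 48 and turned in 3. The robust prior did not enter the list tests, and the values as deposited barely differ from the scaled ones. Their list checks, also with an estimated correlation, therefore repeat the main result and add no support. With control 2 and affected 3 left out the cardiac muscle median turned to 0.65, past the camera threshold at the preset correlation (adjusted p = 0.0107). The oxidative phosphorylation median turned to 0.012 there and its call ended (adjusted p = 0.875). Without single dogs the medians of these 2 lists ranged from -0.96 to 0.11 and from -0.68 to -0.089. With control 2 and affected 3 left out the calls of serotonin handling (adjusted p = 0.156), complement (0.0896), antigen presentation (0.0576), integrins (0.0592) and cell junctions (0.847) ended as well, while collagens (0.00399) and chondrogenic genes (0.0124) were called lower and myofibroblast genes (0.00334) higher. The replicate block called matrix proteases (adjusted p = 0.0443) and myofibroblast genes (0.0490) higher.

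The 20 genes with the smallest p kept their sign in each of 22 refitted settings that tested them. They were picked for no overlap between the groups, so left-out dogs, array weights, another prior or the block could not turn a sign. The stricter filter did not test FCER1G, CALCA, LOC403585, IGFBP2 and TCN2. Among the other named genes, a floor at the 40th percentile turned MMP14 to 0.19 and RUNX2 to -0.0092. Array weights turned TGFB2 to -0.055, MMP2 to -0.48 and COL1A1 to -0.31, and the muscle covariate turned MMP2 to -0.41 and COL1A1 to -0.076. With control 2 and affected 3 left out, TGFB2 was at -0.055, MMP2 at -1.11, COL1A1 at -0.64, COL1A2 at -0.10, BMP2 at -0.12 and PTHLH at -0.055. Without single dogs the signs turned within -0.024 to 0.42 for TGFB2, -0.27 to 0.95 for DES, -0.77 to 0.55 for MMP2, -0.65 to 0.39 for MMP14, -0.52 to 0.70 for COL1A1, -0.072 to 0.56 for COL1A2, -0.74 to 0.29 for COL3A1, -0.24 to 0.0021 for ELN, -1.82 to 0.33 for ACAN, -0.044 to 0.51 for LCK and -0.15 to 0.63 for RUNX2. Scaling moved the median of all probe sets by at most -0.07. The array checks moved by less than the larger of the 2 groups' SDs when any dog was left out, but without affected 2 the difference in median signal went from 9.35 to -2.76 and that in the share at the floor from -0.94 to 0.25, and without affected 3 that in cardiac muscle signal went from -0.56 to 0.018. Low signals limit probe sets near the floor, where differences are bounds.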

Other observations

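Leaving out control 2 and affected 3 together, the cardiac muscle covariate and the genes of this part were chosen after the result was seen, and the fatty acid oxidation list was written after CD36, LPL, SCD, CAT, ACSL1 and PPARA had been seen among the lower genes.

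The values of CILP, ACAN and SOX9, of the chondrogenic and osteogenic list, and of PTN, WIF1 and S100B depended on control 2, the dog with the highest heart muscle signal. The 6 genes were picked for this, and with all dogs that list was not called (camera adjusted p = 0.706). Without control 2 CILP differed by -2.78 ± 0.44 (log2, SE), PTN, a heparin-binding growth factor, by -3.22 ± 0.72, WIF1 by -3.03 ± 0.57, S100B by -2.23 ± 0.42, ACAN, the aggregating proteoglycan of cartilage, by -1.82 ± 0.65 and the chondrogenic transcription factor SOX9 by -1.45 ± 0.43. With all 8 dogs the values were -2.13 ± 0.65, -2.68 ± 0.78, -1.85 ± 1.04, -1.54 ± 0.65, -0.36 ± 1.27 and -0.59 ± 0.77, and none of these passed the adjustment in limma in either setting. With all 8 dogs ACAN and SOX9 differed by less than their errors, and ACAN turned to 0.33 without control 3. With affected 3 left out as well all 6 passed, with adjusted p from 0.0218 to 0.0427 in limma. For each of the 6, control 2 was the lowest control and affected 3 the highest affected dog. Leaving both out could therefore only make the differences more negative, and these adjusted p are no test of a decrease. SFRP4 and BGN were looked at too and also depended on control 2. They went from 0.25 and 0.13 with all dogs to -1.03 and -1.01 without control 2. With affected 3 left out as well these 2 did not pass (adjusted p = 0.125 and 0.141 in limma). In the same setting TNMD, a tendon membrane protein, differed by -3.46 with the smallest adjusted p, 0.00803, the Wnt antagonist FRZB by -2.76, ASPN, a small proteoglycan, by -1.77 and TIMP3 by -1.50. Other probe sets of FRZB, ASPN and TIMP3 were not called in that setting, and with all 8 dogs the 5 of TIMP3 ranged from -0.47 to 0.26. All 128 probe sets called in that setting had the same sign with all 8 dogs, and 71 of them had an unadjusted p under 0.05 there. The dogs of that setting are among the 8, so this is no independent support.

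Several genes outside the lists had higher signals in each affected dog than in every control, and none passed the adjustment in limma. They were the acute phase proteins SERPINA1 at 3.18 ± 0.74 and ITIH3 at 1.397 ± 0.32, the acid sphingomyelinase-like phosphodiesterase SMPDL3A at 3.26 ± 0.83, the aspartic protease NAPSA at 2.31 ± 0.52 and PDPN, a membrane glycoprotein of lymphatic endothelium and activated fibroblasts, at 1.63 ± 0.36. GHR, the growth hormone receptor, at -1.10 ± 0.31, PENK, a precursor of opioid peptides, at -1.47 ± 0.37 and BCKDHB, an enzyme of branched-chain amino acid breakdown, at -1.32 ± 0.33 were lower in each affected dog than in every control. Other probe sets of SERPINA1 and ITIH3 differed by as little as 0.46 ± 0.35 and 0.40 ± 0.33, and another of NAPSA went the other way at -1.23 ± 0.61. The printed NAPSA probe set was at the floor in control 2 and control 4, so the size of its difference depends on the floor.

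Lower CD36 and LPL led to the hypothesis that enzymes of fatty acid oxidation are lower as a group in affected leaflets. Of 30 listed enzymes 17 were measured, none of them in another list, and 15 were lower, with a median of -0.49 and a camera adjusted p of 0.000269 when added to the 32 lists (adjusted p = 0.431 with an estimated correlation, exact permutation p = 0.0571 for the mean over 4 against 4 dogs). HSD17B4, ECHS1 and DECR1 differed by -0.68 ± 0.27, -0.72 ± 0.29 and -0.84 ± 0.38, and by -0.75, -0.45 and -0.47 without control 2. The 4 probe sets of DECR1 ranged from -0.97 to -0.34 with all dogs. With the cardiac muscle list as a covariate the median was -0.33 with 15 of 17 lower, and without control 2 it was -0.25 with 16 of 17 lower. A lower capacity for fatty acid oxidation is a hypothesis, with a group error that the estimated correlation leaves wide. No error was computed for the median under the covariate. A different share of heart muscle and a difference in leaflet cells therefore cannot be told apart here either.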
